A study of Anser cygnoides with 9 samples.

How the data were processed

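The samples were 9 libraries of cultured goose (Anser cygnoides) ovarian granulosa cells in 3 groups of 3: GnRH agonist, GnRH antagonist and blank. Per the series' design text, the ovaries were taken 2 hours before laying and the cells came from preovulatory follicles and from pre-hierarchical follicles of 4 to 12 mm, and the analogue concentrations were chosen by proliferation assays. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. Nothing says whether the libraries of a group came from separate birds or cultures, so p-values measure only the spread between these libraries, which may be technical.

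The authors deposited a table of TPM values with 1371 gene names and 9 columns, one per library, all of which were used. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.1.0, Cufflinks 2.2.1, Cuffdiff and StringTie 1.2.2, without roles. The genome build and annotation, and whether strand was used, are not given in the sources used here. Gene names were used as the table gives them; 1253 of 1371 matched a symbol of the RefSeq annotation of the Taihu goose T2T assembly, which served only to find neighbouring genes. The listed TPM summed to 2.88% to 3.26% of a full set of TPM values, so scaling that uses only these genes sees part of each library. Long noncoding RNA values were not analysed here.

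TPM keeps no depth, so the number of reads per library is unknown. Among 366 genes under 0.5 TPM, which include those listed at 0 in all libraries, values were taken to move in steps of single fragments. The ratios between libraries gave the relative worth of a fragment, from 1.00 in blank replicate 3 to 1.21 in blank replicate 1. Relative to blank replicate 3, each library's worth rested on 72 to 102 gene ratios, of which 16 to 28 lay at the most frequent value. This worth depends on depth and on transcript composition. The method recovered the factors of simulated fragments. That simulation was built on the same steps, so it cannot show that the deposited values follow them.

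Values were taken as log2(TPM + 1), and genes with 1 TPM or more in at least 3 of the 9 libraries were kept, which left 832 and removed 539, of which 52 were listed at 0 in all libraries. Fold changes are on the scale of TPM + 1, which understates the change of genes with low values. Each of the 3 pairwise comparisons was tested with limma 3.58.1 in R 4.3.3, with a linear model of the 3 groups over all 9 libraries and empirical Bayes moderation with a variance trend. Benjamini-Hochberg adjustment was made within each comparison, and genes with an adjusted p under 0.05 were called. An exact permutation test of 3 against 3 libraries cannot go below a two-sided p of 0.1 and was not used for single genes. Differences among the 3 groups were tested with the moderated F-test. Gene lists with 5 or more tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison; 3 of 34 lists qualified (immediate early genes, oxidative phosphorylation and cytosolic ribosomal proteins), and no pathway or marker list with fewer members was tested as a set. Camera with an estimated correlation and fry were run beside it.

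In simulated libraries with 200 of 832 genes changed, limma called 77.3% of changes of 0.5 and 96.4% of changes of 1 on the log2 scale for antagonist against blank, 78.3% and 97.3% for agonist against blank, and 78.1% and 98.3% for agonist against antagonist. Unchanged genes made up 3.87%, 3.94% and 4.85% of the calls. The simulated genes varied independently, and as many changes went up as down. No flow cell or library-wide shift was simulated, so these shares need not hold for the real libraries.

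The groups, tests, gene lists, most of the other ways of analysis and the rule for named genes were fixed before the data were examined. By that rule, the genes named for a comparison had a mean of 5 TPM or more in a group compared and were the 10 with the largest fold change past the threshold in each direction, with places filled up to 5 by the smallest unadjusted p and given as values. From each list, up to 4 called members were named, or else the 2 members with the highest mean TPM. RPL27, and the genes of families chosen after the values were seen, fall outside the rule. Some genes are not reported here.

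The description labels place the libraries on 3 flow cells. H75K3DMXX held agonist replicate 1 and antagonist replicate 2. H77KGDMXX held agonist replicate 2, antagonist replicates 1 and 3 and blank replicate 1. H773TDMXX held agonist replicate 3 and blank replicates 2 and 3. The flow cell was put in the model as a term and, in a fit chosen after the results were seen, as a random block. The log2 worth of a fragment was also put in the model after the results were seen. The other changes of method were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 TPM, the replicate number as a block, library weights, upper quartile, quantile and median of ratios scaling, fits of 2 groups only, no variance trend, a robust prior and leaving out each library. Figures were drawn with matplotlib 3.10.9.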

Results

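Transcript levels were measured in cultured ovarian granulosa cells of Sichuan white geese, the steroid-producing cells that line the follicle around the oocyte. The cells came from small and large yellow follicles of 40-week-old birds. They received alarelin acetate, a peptide analogue of gonadotropin-releasing hormone (GnRH) that activates its receptor, or cetrorelix acetate, a peptide analogue that blocks it, or neither (blank). Each of the 3 groups held 3 libraries, 9 in all. The doses and exposure times of the 2 analogues are not given in the sources used here, so their responses are set side by side at doses that may differ. The deposited table listed 1371 genes in TPM, a share of transcripts corrected for their length, whose sum per library was 28759.5 to 32645, or 2.88% to 3.26% of a full set of TPM values, so it held only part of the transcriptome. The number of reads per library is unknown. Of these genes, 832 reached 1 TPM in at least 3 libraries and were tested.

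The antagonist libraries stood apart from the others on the first principal component of log2(TPM + 1), which took 45.1% of the variance. Their scores were 5.35, 4.14 and 6.90 for replicates 1, 2 and 3, against -5.98, -2.62 and -3.61 for the agonist libraries. The blank libraries scored 2.57, -3.10 and -3.66, so blank replicate 1 lay between its own group and the antagonist group. The 10 genes with the highest TPM took 35.4% to 37.4% of the listed TPM in the antagonist libraries and 37.8% to 39.8% in the other 6.

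**Figure D1:**
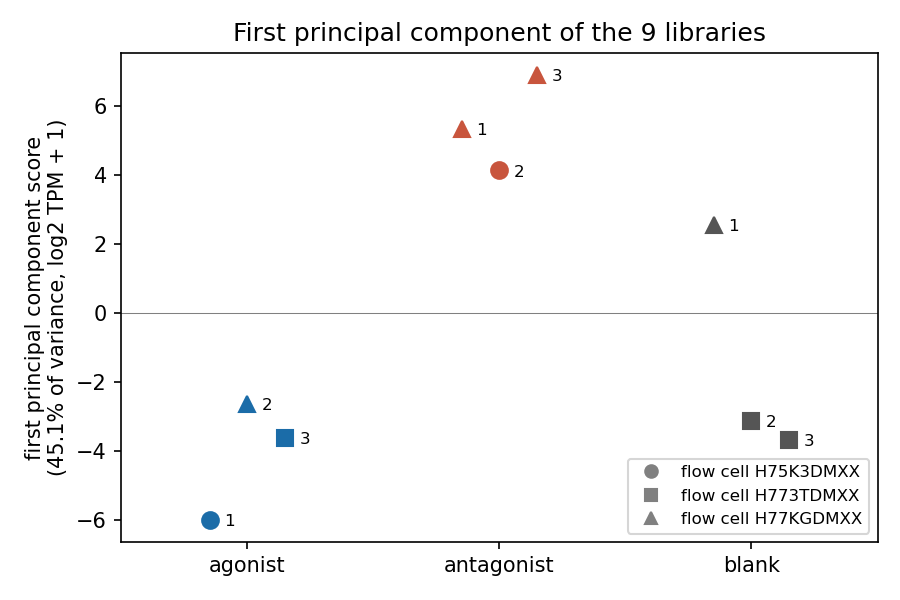
Score of each library on the first principal component of log2(TPM + 1) over the 832 tested genes, by group; numbers are replicates and symbols are flow cells. The 3 antagonist libraries lie between 4.14 and 6.90, above all others, and blank replicate 1 lies at 2.57 while the other blank libraries lie at -3.10 and -3.66.

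The direct comparison of the analogues asked which transcripts differed between activation and blockade of the GnRH receptor. Transcripts of the mitochondrial proteins SIRT3 and SLC25A28 were lower in agonist-treated than in antagonist-treated cells. SIRT3, an NAD-dependent deacetylase, was at 5.21 ± 1.1 TPM with the agonist and 12.5 ± 1.2 TPM with the antagonist (mean ± SD, n = 3 each). SLC25A28, an iron importer of the inner membrane, was at 25.2 ± 1.6 and 48.8 ± 1.8 TPM. EGR1, an immediate early transcription factor, was also lower with the agonist, at 84.1 ± 9.7 TPM against 140 ± 2.9 TPM. ID4, an inhibitor of helix-loop-helix transcription factors, was higher with the agonist, at 9.64 ± 2.6 against 5.71 ± 0.27 TPM. In limma, 213 of the 832 genes passed an adjusted p of 0.05, of which 14 were higher and 199 lower in agonist-treated cells.

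The largest decrease past the threshold, agonist relative to antagonist, among genes at 5 TPM or more was that of SIRT3, whose log2 fold change was -1.14 ± 0.17 (SE; limma, adjusted p = 0.00438). HYI, a hydroxypyruvate isomerase, had the smallest adjusted p of all genes (log2 fold change -0.86 ± 0.10, limma, adjusted p = 0.00302), and EGR1 and SLC25A28 followed with log2 fold changes of -0.73 ± 0.09 and -0.93 ± 0.12 (limma, adjusted p = 0.00363 for each). GYG1, which primes glycogen synthesis, fell by 0.96 on the log2 scale, TPRA1 by 0.88, the chromosome alignment factor CHAMP1 by 0.85, C1H2ORF49 by 0.82, WDR6 by 0.80, the transcription factor subunit CBFB by 0.78 and the microtubule-associated protein MAPT by 0.76. The calls of CHAMP1, CBFB and C1H2ORF49 were lost with quantile normalization and those of C1H2ORF49 and WDR6 with median of ratios scaling. Among the genes higher with the agonist, TXNL4B rose by 0.44 on the log2 scale, DAD1, a subunit of the oligosaccharyltransferase, by 0.41, and FKBP11, a prolyl isomerase of the endoplasmic reticulum, by 0.37. The proteasome subunit PSMB3 rose by 0.37, the histone variant H2AFZ by 0.35, CHMP1A by 0.34, the mitochondrial import factor DNAJC19 by 0.33, RPS3A by 0.31 and the ATP synthase subunit ATP5J2 by 0.30. TXNL4B, PSMB3, DNAJC19 and ATP5J2 no longer passed with the flow cell in the model (log2 fold changes 0.44, 0.30, 0.36 and 0.26 there). RPS3A and ATP5J2 no longer passed with quantile normalization. The calls of DNAJC19 and ATP5J2 were also lost with the replicate number as a block, that of ATP5J2 in the fit of only the 2 groups, and that of RPS3A without a filter on low values. The median log2 fold change of all 832 genes was -0.21, so genes near that value did not stand apart from the rest.

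**Figure D2:**
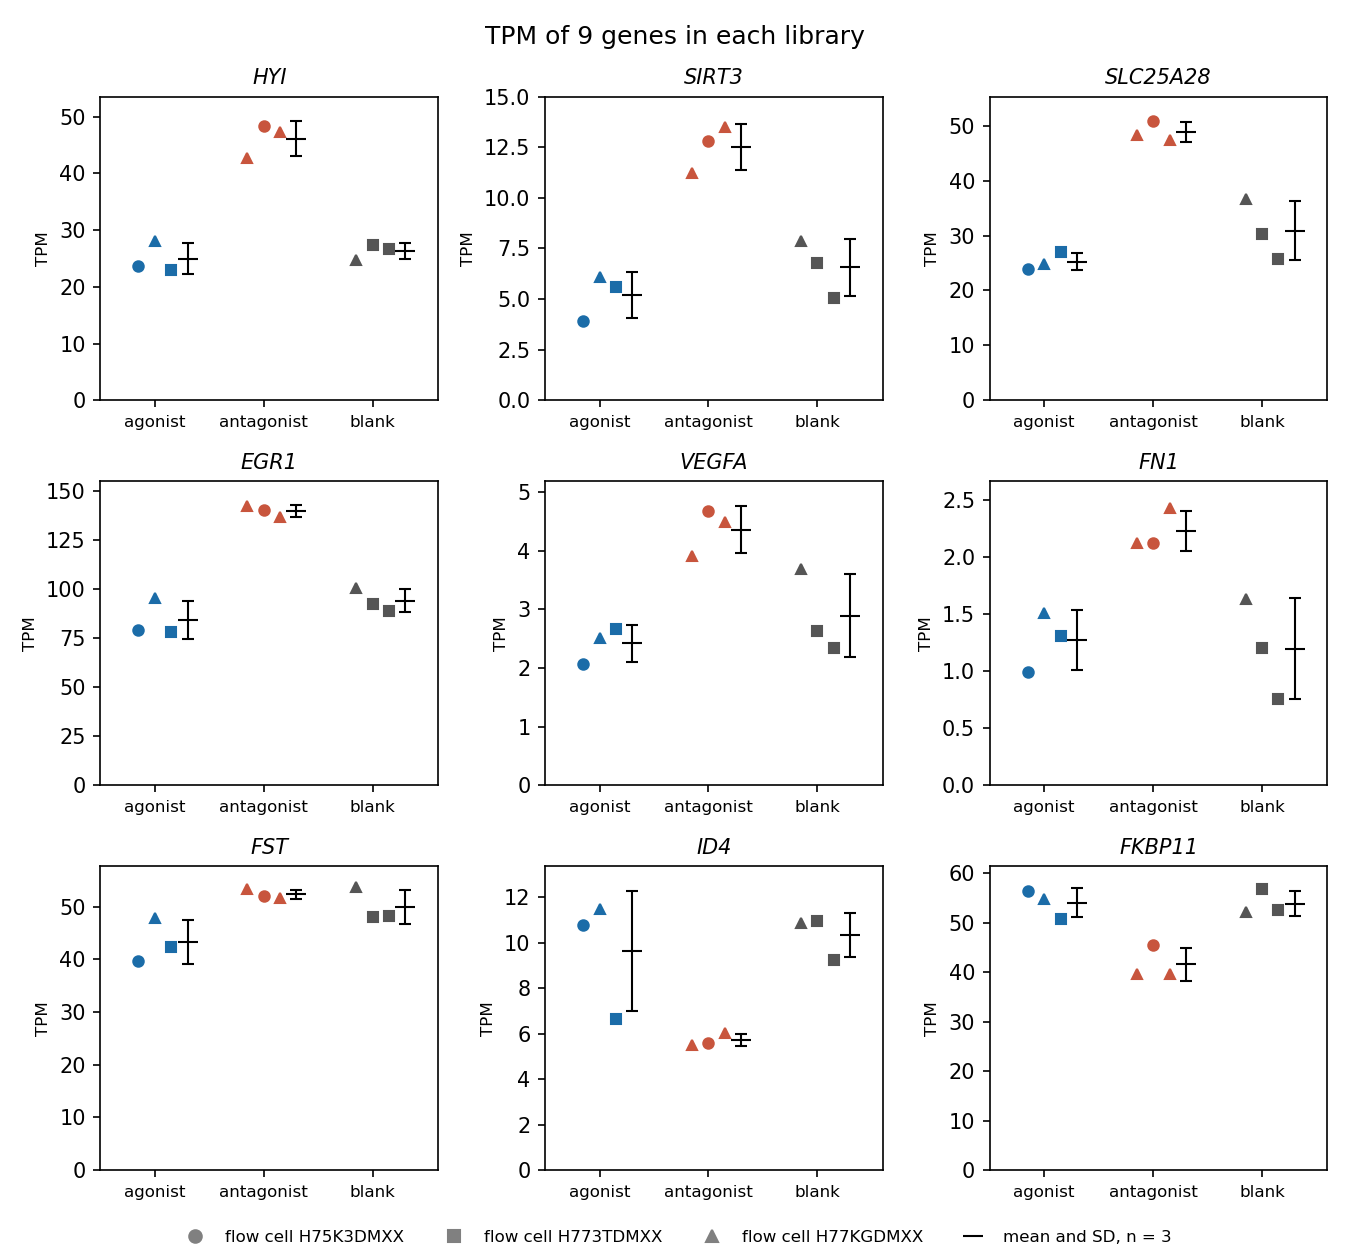
TPM of 9 genes in each library by group, with symbols for flow cells and bars for the mean and SD of 3 libraries; each vertical axis starts at 0. All 3 antagonist libraries lie above the other 6 for HYI, SIRT3, SLC25A28, EGR1, VEGFA and FN1, and below them for ID4 and FKBP11, while FST separates the antagonist libraries from the agonist libraries but not from the blank libraries.

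Among the lists fixed beforehand, called members were spread over several processes. Of the 3 tested genes of GnRH receptor signalling and the 6 immediate early genes, EGR1 was lower with the agonist and no other member passed, and camera gave an adjusted p of 0.50 for the immediate early list. The growth factor VEGFA was lower (log2 fold change -0.65 ± 0.13, limma, adjusted p = 0.013). FN1, which encodes fibronectin, fell by 0.51 on the log2 scale, the isoprenoid enzyme GGPS1 by 0.35, and the complex I subunit NDUFV1 by 0.87, at 0.632 and 1.95 TPM. In lipid storage, ANGPTL4, an inhibitor of lipoprotein lipase, fell by 0.39 and the triglyceride synthesis enzyme DGAT2 by 0.37, and the other 2 tested members did not pass. The focal adhesion protein ZYX fell by 0.35. These calls depended on the method. Those of FN1, NDUFV1 and ZYX were lost with the flow cell in the model (log2 fold changes -0.43, -0.89 and -0.30 there). The calls of FN1 and DGAT2 were lost without a filter on low values, and that of FN1 with the replicate number as a block. Those of FN1, GGPS1, DGAT2 and ZYX were lost under all 3 scalings, that of ANGPTL4 under upper quartile and median of ratios scaling, that of NDUFV1 under quantile and median of ratios scaling and that of VEGFA under quantile normalization. The log2 fold changes nearest 0 over all changes of method were -0.25 for FN1, -0.08 for ANGPTL4, -0.06 for GGPS1, -0.05 for DGAT2 and -0.04 for ZYX. FST, the activin-binding follistatin, fell by 0.27 (limma, adjusted p = 0.0467), but it passed in only 4 of 14 other settings and 2 of 9 fits without 1 library, and after median of ratios scaling its log2 fold change was 0.03.

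The 14 tested cytosolic ribosomal protein genes split. RPL27, RPL30 and RPS3A were higher with the agonist and RPL11 and RPL22 lower, while 9 did not pass. RPL22 no longer passed with the flow cell in the model (limma, adjusted p = 0.0779). Adjusted over the list alone, the counts were also 3 and 2, and over all genes they were 4 and 1 with upper quartile scaling, 0 and 0 with quantile normalization and 6 and 0 with median of ratios scaling. The group means of the 3 that rose lay between 473 and 1040 TPM, and those of RPL11 and RPL22 between 3.10 and 17.5 TPM. The list lay above the other genes in camera (adjusted p = 0.000100, and adjusted p = 0.052 with an estimated correlation). Its median log2 fold change was 0.06, its mean -0.02. The oxidative phosphorylation list, with 9 of its 71 genes tested, did not pass (camera, adjusted p = 0.354).

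The following values did not pass the test, at log2 fold changes of agonist against antagonist. For cell cycle and replication, CCND1 was at -0.17, CCND2 at -0.13, MCM6 at -0.19 and TYMS at -0.22. Among cell cycle inhibitors, CDKN1B was at -0.04 and BTG1 at -0.31. The stress genes PDIA6, MANF and HSPB8 were at 0.19, -0.05 and -0.24. The immune genes IRF7, CEBPD and MYD88 were at 0.03, -0.18 and 0.07. BTC, a ligand of the epidermal growth factor receptor, was at -0.21, GJC1 at -0.0042, SFRP4 at -0.18, FTH1 at -0.02, CAT at -0.29 and EMX2 at -0.14.

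Within the 2 flow cells that held both groups, H75K3DMXX and H77KGDMXX, the median log2 difference over all genes was -0.23 and -0.15. With the flow cell in the model 132 genes passed, 126 of them among the 213. With the relative worth of a fragment in the model, which differs between these groups, 5 genes passed, 4 of them among the 213, with HYI, SLC25A28 and EGR1 among these and SIRT3 not (limma, adjusted p = 0.0578). The split into 14 higher and 199 lower became 35 and 66 with upper quartile scaling, 25 and 27 with quantile normalization and 68 and 50 with median of ratios scaling. Single libraries mattered: 15 genes passed without agonist replicate 1, 17 without antagonist replicate 3, 57 without antagonist replicate 1, 121 without agonist replicate 3 and 140 without antagonist replicate 2.

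The comparison of antagonist and blank asked what blockade of the receptor changed relative to untreated cells. EGR1 was higher in the antagonist libraries, at 140 ± 2.9 TPM against 93.9 ± 6.0 TPM in the blank libraries (mean ± SD, n = 3 each). SIRT3 was higher at 12.5 ± 1.2 against 6.57 ± 1.4 TPM and HYI at 46.1 ± 3.0 against 26.3 ± 1.4 TPM. ID4 was lower at 5.71 ± 0.27 against 10.3 ± 0.97 TPM. In limma, 92 of 832 genes passed, 85 higher and 7 lower with the antagonist. The groups of libraries did not overlap for 33.9% of all tested genes, where chance gives 10% for a single gene. The share was 11.9% for agonist against blank and 48.0% for agonist against antagonist. Genes share the same libraries and the spread of such shares by chance was not computed, so they test nothing.

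HYI shared the smallest adjusted p with 1 other gene (log2 fold change 0.79 ± 0.10 SE, limma, adjusted p = 0.00464), and SIRT3 had the largest fold change past the threshold among genes at 5 TPM or more (0.85 ± 0.17, limma, adjusted p = 0.0268). The other large increases were those of TPRA1 (1.70-fold), DDA1 (1.69-fold), C1H2ORF49 (1.68-fold), GYG1 (1.67-fold), the dynactin subunit DCTN6 (1.61-fold), ITGB1BP1 (1.60-fold), KLHL30 (1.60-fold) and RPL11 (1.58-fold), on the scale of TPM + 1. ID4 fell by 0.76 on the log2 scale, TXNL4B by 0.50, the peroxisomal enzyme DECR2 by 0.43, the mitochondrial ribosomal protein MRPL16 by 0.37 and FKBP11 by 0.37. Of all these, only HYI and ITGB1BP1 passed without a filter on low values. The calls of TPRA1, C1H2ORF49, GYG1, DCTN6 and KLHL30 were lost with the replicate number as a block, and those of DDA1, C1H2ORF49, DCTN6, MRPL16 and FKBP11 with quantile normalization. C1H2ORF49 and DCTN6 passed in 7 of 14 and 7 of 13 other settings. The median log2 fold change of all genes was 0.12.

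From the fixed lists, EGR1 rose with the antagonist by a log2 fold change of 0.57 ± 0.09 (limma, adjusted p = 0.0202). It was the only called member among 3 GnRH signalling and 6 immediate early genes, and the immediate early list did not pass (camera, adjusted p = 0.294). FN1 (log2 fold change 0.57, limma, adjusted p = 0.0435), VEGFA (0.48, limma, adjusted p = 0.049) and the secreted endoplasmic reticulum factor MANF (0.44, limma, adjusted p = 0.0491) passed by a small margin; they passed in 5 of 13, 3 of 13 and 2 of 14 other settings, respectively. Of the 14 ribosomal protein genes, RPL11 and RPL22 rose, RPL22 in only 4 of 14 other settings and 2 of 9 fits without 1 library, and 12 did not pass, while 1 rose and 1 fell with upper quartile or median of ratios scaling, and 1 rose and 0 fell with quantile normalization. Adjusted over the list alone, 2 rose and 2 fell. In camera the list lay below the other genes (adjusted p = 0.00312), with a median log2 fold change of -0.15. It did not pass in camera with an estimated correlation (adjusted p = 0.127) or with a flow cell term (adjusted p = 0.208). After quantile normalization its median was 0.0086 above that of all genes. The 9 tested genes of the 71 in the oxidative phosphorylation list did not pass as a set (camera, adjusted p = 0.0884).

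The following log2 fold changes of antagonist against blank did not pass. DHCR7 was at 0.17, GGPS1 at 0.29, ANGPTL4 at 0.31 and DGAT2 at 0.18. CCND1 was at 0.10, CCND2 at 0.09, MCM6 at 0.12, TYMS at 0.18, CDKN1B at 0.05 and BTG1 at -0.08. SDHD and UQCRFS1 of the respiratory chain were at -0.21 and -0.16. IRF7 was at -0.20, CEBPD at -0.23, MYD88 at -0.08 and HSPB8 at -0.21. BTC was at 0.19, TPM3 at 0.17, ZYX at 0.07, GJC1 at -0.0042, SFRP4 at -0.02, FTH1 at -0.16, CAT at 0.30 and EMX2 at 0.0047.

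With the flow cell in the model 0 genes passed in limma in place of 92, and 199 in place of 252 had an unadjusted p under 0.05. With the relative worth of a fragment in the model 50 passed, 47 of them among the 92. The median size of the log2 fold change of the 92 genes was 0.51 in the main fit. It was 0.45 with the flow cell in the model and 0.43 with the worth of a fragment in the model. Within H77KGDMXX, the only flow cell with both groups (2 antagonist libraries and 1 blank library), it was 0.34, and the median over all genes was 0.04. The split of 85 higher and 7 lower became 62 and 14, 30 and 11, and 35 and 24 under upper quartile, quantile and median of ratios scaling, and the count was 212 without blank replicate 1, 50 and 57 without agonist replicate 1 or 3, 8 without antagonist replicate 2, and 2 without any one of antagonist replicates 1 and 3 and blank replicates 2 and 3.

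The comparison of agonist and blank asked what activation of the receptor changed. No gene passed in limma (smallest adjusted p = 0.193), and 102 of 832 had an unadjusted p under 0.05. The neuronal differentiation gene CEND1 was at 8.11 ± 1.6 TPM with the agonist and 2.58 ± 0.81 TPM in blank cells, a log2 fold change of 1.36 with a 95% interval of 0.60 to 2.12 before adjustment. The splicing factor subunit SF3B5 was at 126 ± 5.3 and 254 ± 77 TPM, a log2 fold change of -0.96. EGR1, at 84.1 ± 9.7 and 93.9 ± 6.0 TPM, differed by -0.16 on the log2 scale (limma, adjusted p = 0.524).

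Other genes with the smallest unadjusted p were ITGB1BP1 (log2 fold change 0.47), HYPK (0.90), MANF (0.38) and TAX1BP3 (0.32) above 0, and POMK (-0.54), the phosphatase PGP (-0.71), CHAMP1 (-0.62) and LHFPL5 (-0.58) below 0. Their adjusted p in limma was 0.275 or more. The median width of a gene's 95% interval was 0.26 to either side on the log2 scale, or 1.19-fold. Without agonist replicate 2, 67 genes passed, 6 higher and 61 lower, and with library weights 12 passed, all lower.

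None of the fixed lists passed for agonist against blank. Camera gave an adjusted p of 0.383 for ribosomal protein genes and 0.409 for both the immediate early and the oxidative phosphorylation lists. JUN was at a log2 fold change of -0.11, RHOB at 0.03, FST at -0.20, BMP4 at -0.10, VEGFA at -0.17, SPARC at -0.08 and FN1 at 0.06. DHCR7 and GGPS1, from the list of cholesterol synthesis and uptake, were at -0.24 and -0.06. CCND1 was at -0.07, CCND2 at -0.04, MCM6 at -0.07, TYMS at -0.05, CDKN1B at 0.01 and BTG1 at -0.39. PDIA6 was at 0.18, HSPB8 at -0.45, SDHD at -0.17, UQCRFS1 at -0.24, RPL7 at -0.03 and RPS3A at 0.08. IRF7 was at -0.18, CEBPD at -0.41, MYD88 at -0.02, TPM3 at 0.00089, ZYX at -0.28, GJC1 at -0.0084 and SFRP4 at -0.20. ANGPTL4 was at -0.08, DGAT2 at -0.18, BTC at -0.02, FTH1 at -0.18, CAT at 0.01 and EMX2 at -0.14.

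**Figure D3:**
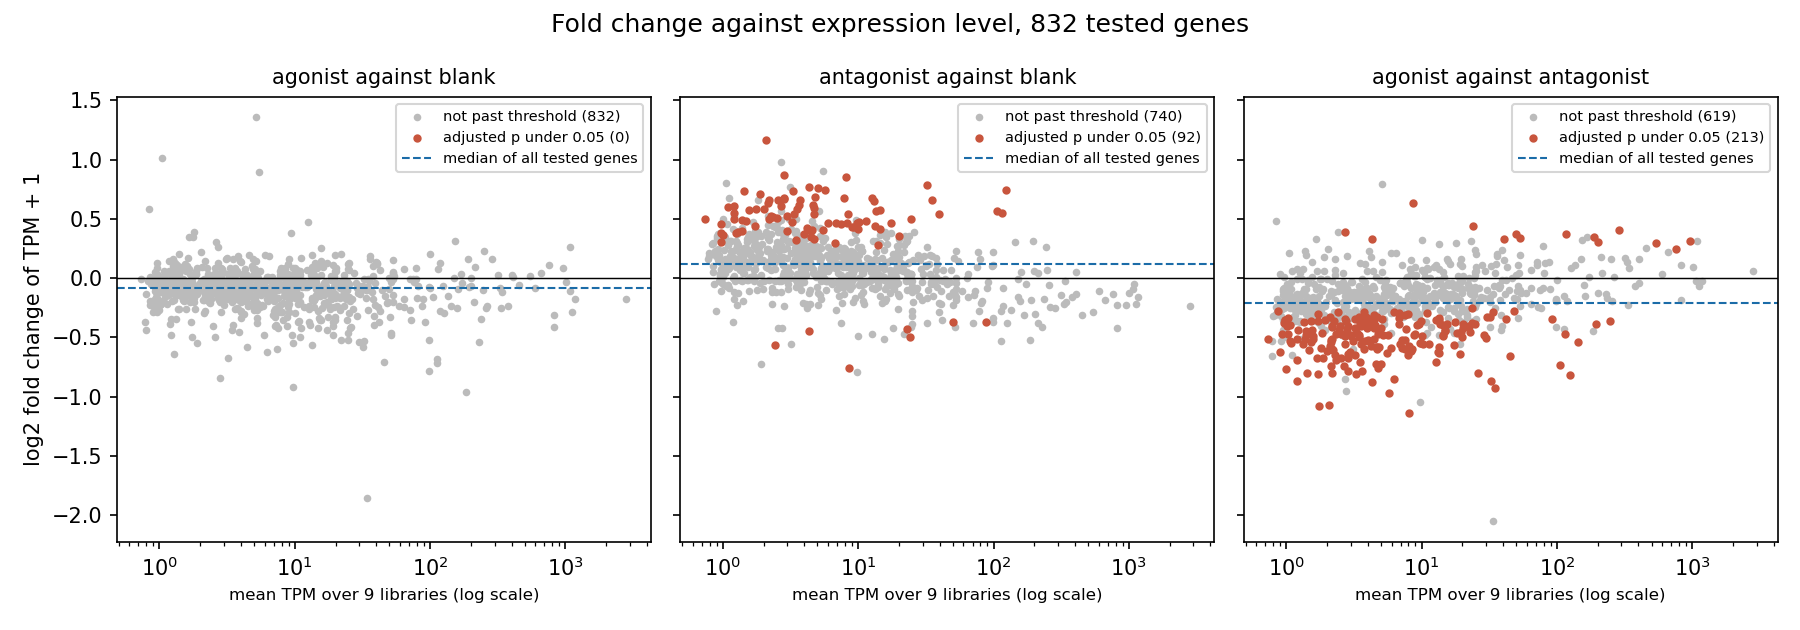
Log2 fold change of TPM + 1 against mean TPM (log axis) for 832 genes in the 3 comparisons, with genes past an adjusted p of 0.05 in red and the median of all genes as a dashed line. No gene passes for agonist against blank, 92 pass for antagonist against blank and 213 for agonist against antagonist; the median line lies at -0.08, 0.12 and -0.21.

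Of the 92 genes called for antagonist against blank, 81 were also called for agonist against antagonist, all in the same direction of the antagonist. Both comparisons use the same 3 antagonist libraries, which makes such overlap arise without a treatment effect, and its size without one was not computed. Among the 213 genes of the direct comparison, HYI, SIRT3 and EGR1 included, the blank mean lay between the 2 treated means in 180. The blank mean was closer to the agonist mean in 171. The 213 genes were selected for a gap between the treated means, which favours a blank mean between them without a treatment effect. The counts without an effect were not computed, so 180 and 171 test nothing. Flow cell H773TDMXX held 2 blank libraries and 1 agonist library but no antagonist library. Closeness of blank to agonist therefore cannot be told apart from the flow cell here. A moderated F-test in limma found a difference among the 3 groups in 130 genes, and in 0 with the flow cell in the model, where 284 had an unadjusted p under 0.05.

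Across genes, the agonist and antagonist effects against the shared blank libraries correlated with Pearson r = 0.358 and Spearman rho = 0.30; genes are not independent replicates. Unchanged groups simulated with shared simulated blank libraries, each gene drawn independently, gave a mean r of 0.504 (0.235 to 0.696) and rho of 0.469 (0.386 to 0.529). The covariance was 0.0176 against a simulated 0.0135 (0.0067 to 0.0257), a difference of 0.0040. Both effects had the same sign in 43.8% of genes, against a simulated 66.9% (62.4% to 72.1%). That share depends on the opposite medians of -0.08 and 0.12, which changed with scaling, so it decides nothing. The observed r and covariance lay within the simulated ranges and rho below its range. The independent draws lack shifts shared by the genes of a library, so the place of rho decides nothing. With 0 agonist calls no shared call was possible, and 3 blank libraries cannot be split with 2 in each part.

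Most genes that mark the tissue were not analysed here: the receptors GNRHR, FSHR and LHCGR, the steroid synthesis genes STAR, CYP11A1, HSD3B1 and CYP19A1, and GNRH1, INHA, AMH, FOXL2, PCNA and MKI67 were not among the 1371 listed genes. Of 1009 genes in the 34 fixed lists, 88 were listed and 68 tested. The steroid synthesis and apoptosis lists had 1 listed gene each and 0 tested. Of 9 cell type marker lists, only the endothelial list had a listed gene, CDH5, which was under the filter, so the cell composition of the cultures was not measured.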

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

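The fits with the flow cell as a random block and with the worth of a fragment, the differences within flow cells and the gene families were chosen after the results were seen; all other changes of method in this part were chosen before. Of 52 named results past the threshold, every one kept its sign under all alternatives except FST, agonist against antagonist, after median of ratios scaling (log2 fold change 0.031). The calls of EGR1, HYI, SIRT3 and SLC25A28 for agonist against antagonist also held with any 1 library left out. The causes of the shifts were not tested. Fewer genes were tested at a mean of 5 TPM, and fewer libraries were fitted with 1 left out. All chosen changes of method were run, and depth in reads is unknown, so its effect was not measured.

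Counts for agonist against blank were 12 with library weights and 0 to 67 with 1 library left out, and 0 otherwise. Antagonist against blank, 92 genes, gave 42 and 61 with pseudocounts of 0.1 and 0.5, 17 without a filter, 26 at a mean of 5 TPM, 0 with a flow cell term, 41 with the flow cell as a random block, 348 with library weights, 41 with quantile normalization, 59 with median of ratios scaling and 2 to 212 with 1 library left out. Agonist against antagonist, 213 genes, gave 86 at a mean of 5 TPM, 132 with a flow cell term, 369 with library weights, 101 with upper quartile scaling, 52 with quantile normalization, 118 with median of ratios scaling and 15 to 295 with 1 library left out. With the relative worth of a fragment in the model the counts were 0, 50 and 5 for agonist against blank, antagonist against blank and agonist against antagonist. The 3 groups together, 130 genes, gave 72 without a filter, 46 at a mean of 5 TPM, 0 with a flow cell term, 422 with library weights, 71, 37 and 66 with upper quartile, quantile and median of ratios scaling, and 7 to 252 with 1 library left out (18 without agonist replicate 1, 68 without agonist replicate 3, 8, 11 and 7 without antagonist replicates 1, 2 and 3, 241, 43 and 98 without blank replicates 1, 2 and 3). The scalings moved the all-gene median from 0.12 to 0.06, -0.0088 and -0.03 for antagonist against blank and from -0.21 to -0.04, 0.02 and 0.03 for agonist against antagonist.

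Nothing in the labels says that the replicate numbers pair libraries across groups. After the group means were removed, 3 of 9 same-numbered pairs of libraries correlated above 0.1 (-0.12 to 0.22). For 7 of 9 libraries, the best correlated library of another group had their own replicate number. The count that arises without pairing was not computed, so a pairing stays open. With the number as a replicate block, 0, 27 and 166 genes passed for agonist against blank, antagonist against blank and agonist against antagonist, and 45 among the 3 groups.

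For the ribosomal list, antagonist against blank gave an adjusted p of 0.127 with an estimated correlation, 0.568 with fry, 0.208 with a flow cell term and 0.00077 to 0.023 with 1 library left out. Agonist against antagonist gave 0.052 with an estimated correlation, 0.440 with fry and 2.0e-05 to 0.0091 with 1 library left out. The oxidative phosphorylation list, antagonist against blank, ranged from 0.029 to 0.367 with 1 library left out. Uncalled lists changed direction with fry at adjusted p of 0.493 (ribosomal, agonist against blank), 0.817 (immediate early, antagonist against blank) and 0.257 (immediate early and oxidative phosphorylation, agonist against antagonist), and with a flow cell term at 0.968 (oxidative phosphorylation, agonist against blank); fry does not compare a list with other genes. With 1 library left out they ranged from 0.295 to 0.736 and 0.138 to 0.970 (immediate early, agonist against blank and against antagonist) and 0.210 to 0.928 (oxidative phosphorylation, agonist against blank). The correlation of effects across genes, 0.358, ranged from 0.200 to 0.530 with 1 library left out.

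The 87 named results not past the threshold changed sign in 153 of 1976 alternative fits, with 0 of these past the threshold, and passed in 35 fits without a sign change. These are log2 fold changes. With a flow cell term, signs changed for agonist against blank RHOB -0.042, CDKN1B -0.012, BTC 0.023, RPL7 0.013, TPM3 -0.0040 and for antagonist against blank CDKN1B -0.014, EMX2 -0.17 and for agonist against antagonist CDKN1B 0.0012, MANF 0.026, GJC1 0.11. With library weights, signs changed for agonist against blank RHOB -0.023, CCND2 0.012, TYMS 0.031, GJC1 0.014, CAT -0.092 and for antagonist against blank GJC1 0.042, EMX2 -0.050. With upper quartile scaling, signs changed for agonist against blank GGPS1 0.032, JUN 0.033, CCND1 0.055, CCND2 0.033, MCM6 0.065, TYMS 0.084, BMP4 0.041, SPARC 0.065, BTC 0.045, RPL7 0.11, MYD88 0.087, GJC1 0.12, ANGPTL4 0.068 and for antagonist against blank CDKN1B -0.015, ZYX -0.00014, EMX2 -0.032 and for agonist against antagonist CCND1 0.013, MCM6 0.0018, CDKN1B 0.17, MANF 0.14, CEBPD 0.033, GJC1 0.18, FTH1 0.19. With quantile normalization, signs changed for agonist against blank EGR1 0.040, CCND1 0.077, CCND2 0.037, MCM6 0.058, TYMS 0.070, BMP4 0.049, SPARC 0.047, BTC 0.065, SDHD 0.011, MYD88 0.059, GJC1 0.097 and for antagonist against blank CCND1 -0.0039, CCND2 -0.077, BTC -0.0065, CEBPD 0.084, DGAT2 -0.038, FTH1 0.0032, EMX2 -0.22 and for agonist against antagonist CCND1 0.081, CCND2 0.11, MCM6 0.035, TYMS 0.0034, BTC 0.071, MANF 0.15, HSPB8 0.052, GJC1 0.21, SFRP4 0.12, EMX2 0.16. With median of ratios scaling, signs changed for agonist against blank GGPS1 0.016, JUN 0.0078, CCND1 0.033, CCND2 0.021, MCM6 0.042, TYMS 0.062, BMP4 0.017, SPARC 0.040, BTC 0.035, RPL7 0.088, MYD88 0.070, GJC1 0.098, ANGPTL4 0.043 and for antagonist against blank DHCR7 -0.0049, CCND1 -0.065, CCND2 -0.0051, MCM6 -0.047, CDKN1B -0.14, TPM3 -0.014, ZYX -0.12, EMX2 -0.097 and for agonist against antagonist CCND1 0.098, CCND2 0.026, MCM6 0.089, TYMS 0.058, CDKN1B 0.27, MANF 0.23, CEBPD 0.13, GJC1 0.27, SFRP4 0.046, FTH1 0.29, CAT 0.0049, EMX2 0.022. With the flow cell as a random block, signs changed for agonist against blank TPM3 -0.00057 and for antagonist against blank EMX2 -0.046 and for agonist against antagonist GJC1 0.036. With 1 library left out, the ranges that crossed 0 were for agonist against blank RHOB -0.065 to 0.14, BTC -0.10 to 0.036, RPL7 -0.085 to 0.012, TPM3 -0.051 to 0.060, GGPS1 -0.11 to 0.0061, CDKN1B -0.030 to 0.060, FN1 -0.091 to 0.20, CAT -0.15 to 0.10, JUN -0.21 to 0.030, BMP4 -0.23 to 0.041, MYD88 -0.052 to 0.0088, GJC1 -0.17 to 0.19, CCND2 -0.11 to 0.0037, TYMS -0.11 to 0.029 and for antagonist against blank SFRP4 -0.070 to 0.012, GJC1 -0.082 to 0.11, EMX2 -0.085 to 0.10, BTG1 -0.18 to 0.0019 and for agonist against antagonist FTH1 -0.17 to 0.066, IRF7 -0.10 to 0.16, CDKN1B -0.084 to 0.0056, CEBPD -0.33 to 0.021, GJC1 -0.17 to 0.20, MYD88 -0.0041 to 0.17, MANF -0.093 to 0.0046.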

Other observations

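The tests in this part were chosen after the results they address were seen, except the counts over other splits of the libraries and the abundance trend with 1 library left out. The gene families were also chosen after the values were seen.

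Of 15 gene families chosen and tested on the same values, 2 passed in camera for agonist against antagonist and 0 with an estimated correlation, so what follows describes values and tests nothing. Of 18 genes of the endoplasmic reticulum and Golgi, DAD1 and FKBP11 were higher and SRP72 lower with the agonist than with the antagonist, and 15 did not pass. Camera placed the family above the other genes (adjusted p = 0.0106, and p = 0.0688, adjusted p = 0.258, with an estimated correlation). Its own median log2 fold change was -0.07, and it was 0.11, 0.09 and 0.18 under upper quartile, quantile and median of ratios scaling, so its place is relative to all genes; 5, 4 and 6 members were then higher and 0 lower. Of 6 genes of mitochondrial protein import, DNAJC19 was higher and 5 did not pass (camera, adjusted p = 0.0125, and p = 0.0343 with an estimated correlation, adjusted p = 0.258). SMIM15, which did not pass, was listed at 0 in agonist replicate 2 and at 55.0 and 15.9 TPM in agonist replicates 1 and 3.

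The called genes lay mostly on one side, higher with the antagonist. A single scaling factor per library does not account for all of the calls: after median of ratios scaling 64 of the 213 and 42 of the 92 genes still passed in the same direction. The other calls were lost, and for them this explanation stays open. It stays open for the one-sidedness: for antagonist against blank the 84 genes with the highest mean TPM had a median log2 fold change of -0.14 while all genes had 0.12, but the scaling changed the split from 85 higher and 7 lower to 35 and 24, and for agonist against antagonist the same 84 genes were at -0.033 (-0.10 to 0.05). For agonist against antagonist, 126 of the 213 genes were still called with the flow cell in the model, which argues against it as the whole source. The other calls were lost, and for them the flow cell stays open. The median size of the log2 fold change of the 213 moved from 0.47 to 0.43 and its median SE from 0.116 to 0.103. For antagonist against blank the flow cell cannot be told apart from the treatment, because only 1 blank library shared a flow cell with antagonist libraries. With the flow cell in the model 0 of the 92 genes remained. The median size of their log2 fold change moved from 0.51 to 0.45 and its median SE from 0.124 to 0.132, with fewer degrees of freedom. Within the shared flow cell the all-gene median was 0.04 in place of 0.12. With the relative worth of a fragment in the model, 47 of the 92 antagonist against blank calls remained. The median SE of the 92 moved from 0.124 to 0.104. This argues against depth or transcript composition as their whole source, only as far as the estimated worth measures it. For agonist against antagonist, 4 of the 213 remained with this worth in the model. The median size of the log2 fold change of the 213 moved from 0.47 to 0.34 and its median SE from 0.116 to 0.122. This worth was 1.03 to 1.08 in the agonist and 1.11 to 1.18 in the antagonist libraries. Depth or transcript composition therefore cannot be told apart from the treatment there. Overlap with a neighbouring gene was found for 33.8% of the called genes placed on the reference and 33.4% of the others, which argues against shared reads as the source of the 213 calls; a treatment effect stays open as a hypothesis.

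Blank replicate 1 lay between the other blank libraries and the antagonist libraries. The flow cell may contribute: its libraries also scored highest within the agonist and the antagonist group, but these are too few to decide (exact one-sided p = 0.111, the smallest that this design can give). Depth or transcript composition may contribute as well, since a fragment was worth 1.21 times as much TPM in blank replicate 1 as in blank replicate 3, against 1.11 to 1.18 in the antagonist and 1.03 to 1.08 in the agonist libraries. These stay open, as does a difference between the cultures, which was not tested.

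Fold changes of antagonist against blank fell with mean expression (Spearman -0.39 across genes, which are not independent replicates). The lean is not due to 1 library: the value nearest 0 with a library left out was -0.34. The biological and other technical explanations were not tested.

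Counts over other splits bear on chance. The 10 splits of the 6 libraries of a pairwise comparison are too few for a share under 0.05. The real split gave 213 genes for agonist against antagonist (1 of 10 splits as large, highest other 0) and 92 for antagonist against blank (1 of 10, highest other 1). For agonist against blank it gave 0, so all 10 of the 10 splits were as large, and the highest other gave 1. For the 3 groups together, 1 of 100 drawn splits of the 9 libraries, the real one itself, gave as many as 130 genes, and the highest other gave 97. This makes chance unlikely there, without excluding it, if all 9 libraries are exchangeable. They share flow cells unevenly, and with the flow cell in the model the same test gave 0 genes. The split with 97 genes kept the 3 antagonist libraries together.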
